A study of Homo sapiens with 20 samples.

How the data were processed

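Gene expression was measured on 20 oligonucleotide arrays of the HG-U133 Plus 2.0 design, each hybridised with biotin-labelled total RNA from a culture of an established human tumour cell line. The 10 groups are 5 lines, each untreated or treated with danusertib, with 2 biological replicates per group per the labels. Treated cultures received 1 µM danusertib for 24 h. The labels state that the compound was dissolved in DMSO, and they do not state whether the untreated cultures received that solvent. No label gives a processing date or batch.

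The authors deposited a single table of expression values on the log2 scale, made with RMA (robust multi-array average, which corrects background, quantile-normalises the arrays and summarises the probes of each probe set). The software, its version and the chip description file are not given. The table holds 54675 probe sets, and 62 of them are control probe sets. Sorted values were nearly equal between arrays, and genes were not centred. RMA values are relative to a common distribution, so a change in total RNA per cell cannot be seen in them. Values near the lower end of the scale are mostly background, since RMA gives every probe set a value.

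Probe sets were assigned to genes with the annotation of the platform. Of all probe sets, 41097 have 1 gene symbol, 1801 have several and 11777 have none. Both latter kinds were left out of gene results. The 41097 probe sets belong to 19775 genes, and each gene is represented by its probe set with the highest mean over the 20 arrays. Genes were tested when the mean of at least 1 group was above 5.13, the median of all values, which left 14603 genes and set aside 5172. No reference genome was at hand, so no chromosomal positions are given. Genes to which this annotation assigns no probe set with 1 symbol, among them TP53, have no value here. Their probe sets may be among those with several symbols or none.

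Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 for tables and figures. A linear model with 10 group means was fitted to the 20 arrays, with empirical Bayes moderation of the variances. It has 10 residual degrees of freedom, and the prior adds 2.9. Contrasts gave the treatment effect in each line, its average over the 5 lines, the difference in effect between both breast lines and the difference between both colon lines. A moderated F test asked whether the effect varied among the 5 lines. Because tp53 status is a property of a line, the comparison of tp53 WT with tp53 mut lines used the 5 line differences as replicates, 3 against 2, in limma. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Arrays of replicates give p-values that refer to these lines in culture, and the p-value of the average refers to these 5 lines and not to tumour lines in general. The labels do not state that equal replicate numbers mark the same culture day, so no block was used and a block was kept as an alternative. Deviations of untreated and treated arrays with equal numbers from their group means correlated between -0.05 and 0.13 within lines.

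Gene lists fixed before the data were examined were tested with camera, which compares the genes of a list with all other genes, at a preset correlation of 0.01 between genes, and with fry, which asks whether the genes of a list move one way on balance. There were 21 lists with at least 5 tested genes, and adjusted p-values of lists were computed over the lists of a comparison. The lists cover p53 targets, mitotic genes, G1/S and replication genes, histone genes, apoptosis regulators, NF-kB and secretory inflammation genes, interferon response genes, lysosome and autophagy genes, cholesterol synthesis genes, YAP/TAZ target genes, ERK output genes, integrated stress and ER stress genes, estrogen response genes, epithelial genes, colon, luminal breast, basal breast, fibroblast, leukocyte and endothelial markers, and reference genes. Some genes are in more than 1 list, such as FAS among p53 targets and apoptosis regulators.

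Genes are named by a rule also fixed before the data were examined. It takes the 5 largest rises and 5 largest falls at adjusted p under 0.05 in each line and in each difference between a pair of lines. For the average it takes the 10 largest each way among genes with the same sign in all 5 lines. For tp53 status, where fewer genes passed, it takes the 5 smallest p-values each way. It adds AURKA, AURKB, PLK1, CCNB1, TP53, CDKN1A and MDM2 in every comparison, and up to 4 members of each list with the smallest adjusted p. Other genes that are named were chosen after their values were seen, and the text says so.

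The model was tested on simulated data with the variances of these arrays. Simulated changes of 1 on the log2 scale were recovered in 96% to 99% of genes in single lines, and changes of 0.5 in 55% to 71%. For tp53 status, a simulated difference of 1 was recovered in 93% of genes when lines did not differ otherwise. It was recovered in 10% when they differed at least as much as these lines do, and a difference of 2 was then recovered in 76%. That spread was taken from the observed differences, which also hold the variation of arrays, so it was too wide. Each size of change was given to only 66 or 67 genes, fewer than changed in any of these lines, and adjusted p-values depend on that number. The number of arrays limits the precision of every value.

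Alternatives comprised no filter, a filter at the 75th percentile of all values (7.25), the mean of a gene's probe sets, every probe set as its own feature, renewed quantile normalisation, centring of arrays on their medians, eBayes with trend and robust settings, replicate numbers as a block, only the 4 arrays of a line, a fold of at least 1.5, lines as replicates for the average, arrays as replicates for tp53 status, omission of each line and of each array in turn, and an estimated correlation between genes for the lists. All were chosen before the data were examined, except an alternative with only probe sets that are not marked as shared between transcripts or genes. Nothing was left out of the deposited table except the probe sets named above.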

Results

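The data are expression profiles of 5 human tumour cell lines with and without danusertib, an inhibitor of the Aurora kinases, which act in mitosis. The lines are MCF7 and MDA-MB-468 from breast carcinoma, HCT-116 and Colo205 from colon carcinoma, and A2780 from ovarian carcinoma. The labels give MCF7, HCT-116 and A2780 as tp53 WT and MDA-MB-468 and Colo205 as tp53 mut. Each line has 2 untreated cultures and 2 cultures treated with 1 µM danusertib for 24 h, which makes 20 arrays. The title of the series asks for signatures of pathways under the inhibitor, and the design sets lines of both tp53 states and of several tissues side by side.

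Array medians lay between 5.09 and 5.16 on the log2 scale, lower quartiles between 3.562 and 3.671 and upper quartiles between 7.149 and 7.302. Replicate arrays correlated across all probe sets with Pearson coefficients between 0.9959 and 0.9972 (across probe sets, which are not independent replicates), and the SD between replicates lay between 0.102 and 0.135. The difference between 3' and 5' probe sets of ACTB was 0.04 to 0.26 and was higher in treated than in untreated arrays of every line, by 0.03 to 0.07. For GAPDH the difference between 3' and 5' was -0.11 to -0.05, and treated minus untreated lay between -0.03 and 0.01.

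The first 4 principal components held 35.8%, 23.4%, 19.4% and 17.3% of the variance and separated the lines, and component 5, with 2.0%, separated untreated from treated arrays in every line. Luminal and basal breast markers were highest in a breast line and colon markers in a colon line, but colon markers were not raised in HCT-116. No list covers ovarian markers. In untreated cultures the median of luminal breast markers was 10.52 in MCF7, 8.82 in MDA-MB-468, 7.56 in Colo205, 4.94 in HCT-116 and 4.71 in A2780. That of basal breast markers was 9.90 in MDA-MB-468, and EGFR was 13.26 in MDA-MB-468. The median of colon markers was 6.73 in Colo205 and 4.93 in HCT-116, against 4.78 to 5.11 in the other lines. Epithelial genes had a median of 5.37 in A2780 and 9.43 to 10.38 in the other lines, and fibroblast markers had a median of 7.65 in A2780 and 4.78 to 5.31 elsewhere. Leukocyte and endothelial markers had medians of at most 5.47 in every group.

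The first question is which transcripts each line changes after 24 h of danusertib. Among 14603 genes tested, 2378 changed in MCF7, with 831 higher and 1547 lower. MDA-MB-468 changed 2027 genes, with 1012 higher and 1015 lower. In HCT-116, 3756 genes changed, with 1849 higher and 1907 lower. In Colo205, 3139 genes changed, with 1517 higher and 1622 lower. A2780 changed 7403 genes, or 50.7% of those tested, with 3787 higher and 3616 lower. The balance of higher and lower genes depends on the scaling. After renewed quantile normalisation it was 996 higher and 1316 lower in MCF7, 957 and 1075 in MDA-MB-468, 2021 and 1841 in HCT-116, 1586 and 1562 in Colo205 and 3825 and 3598 in A2780. After centring arrays on their medians it was 680 and 1753, 1184 and 848, 1611 and 2037, 1601 and 1496, and 3725 and 3670 in the same order. Most changes were small. Changes of at least 2-fold among these genes numbered 6 higher and 12 lower in MCF7, 18 higher and 18 lower in MDA-MB-468, 65 higher and 180 lower in HCT-116, 45 higher and 28 lower in Colo205, and 509 higher and 471 lower in A2780. The SD of log2 changes over all genes tested was 0.22 in MCF7, 0.21 in MDA-MB-468, 0.31 in HCT-116, 0.25 in Colo205 and 0.53 in A2780.

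**Figure D1:**
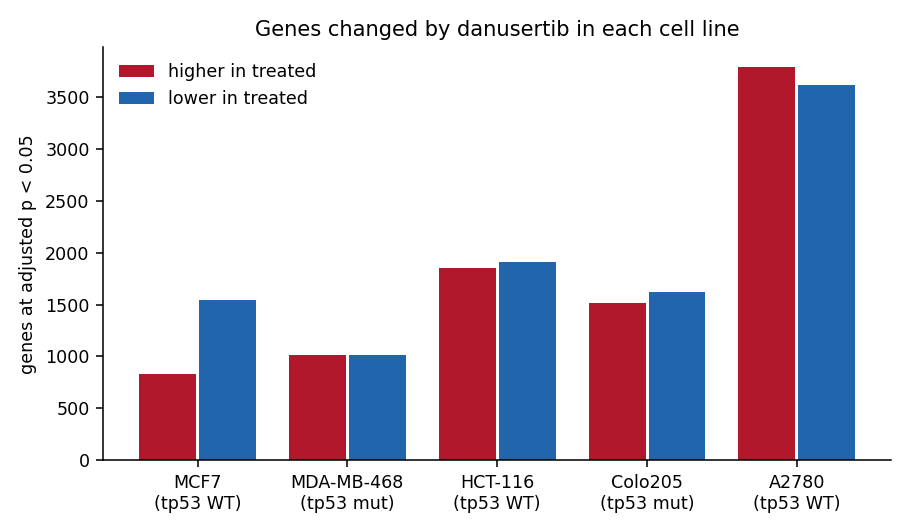
Number of genes (vertical axis) higher (red) or lower (blue) in danusertib-treated than in untreated cultures at adjusted p under 0.05 in each cell line (horizontal axis), n = 2 arrays per group. The counts run from 831 genes higher in MCF7 to 3787 genes higher in A2780.

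In MCF7 the largest rise was that of GDF15, by 1.56 ± 0.06 (log2 change ± SE), from 8.56 to 10.12. Next were H3C6 at 1.23 ± 0.12, TP53INP1 at 1.22 ± 0.11, FAS at 1.19 ± 0.10 and H4C8 at 1.13 ± 0.08. Here and below, ± gives the SE of the contrast, with n = 2 arrays per group, or with 3 against 2 lines for tp53 status. GDF15 rests on a probe set marked as shared, and its other probe sets had mean levels of 4.24 and 4.50, below the filter. The largest falls were those of HMCN1, at -1.59 ± 0.20, LHX2 at -1.47 ± 0.15, GJA1 at -1.31 ± 0.11, HELLS at -1.24 ± 0.10 and SH3PXD2A at -1.23 ± 0.13. GJA1 fell from 4.56 to 3.25, a range near background. All of these had adjusted p of at most 0.00016.

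In MDA-MB-468 the largest rises were those of the histone genes H2AC6, by 1.95 ± 0.05, H3C6 by 1.83 ± 0.12, H2BC5 by 1.77 ± 0.07 and H2BC21 by 1.66 ± 0.12, followed by CCL20, by 1.61 ± 0.10, from 3.83 to 5.43. The largest falls were those of OLR1, at -1.96 ± 0.14, CRISP3 at -1.83 ± 0.17, GABRP at -1.78 ± 0.11, MSMB at -1.63 ± 0.11 and IL7R at -1.40 ± 0.11. These 5 genes started from 5.36 to 6.61 and, in treated cultures, lay between 3.53 and 5.20. The highest adjusted p among the 10 genes was 2.7e-05.

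In HCT-116 the largest rises were those of H2BC5, by 3.08 ± 0.07, H3C6 by 2.46 ± 0.12, H2AC6 by 2.46 ± 0.05, TP53I3 by 2.42 ± 0.06, from 8.03 to 10.45, and H2BC9 by 2.23 ± 0.09. The largest falls were those of MYB, at -2.59 ± 0.07, from 7.66 to 5.07, CCNE2 at -2.07 ± 0.06, DTL at -2.04 ± 0.05, ZNF367 at -1.95 ± 0.06 and TCF19 at -1.85 ± 0.09. The highest adjusted p among them was 9.8e-09.

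In Colo205 the largest rise was that of RNA45SN5, the 45S ribosomal RNA precursor, by 2.71 ± 0.15, from 6.52 to 9.23. The other probe set assigned to RNA45SN5 rose by 2.11 in Colo205 and changed by at most 0.47 in the other lines. H2BC5 rose by 2.11 ± 0.07, H3C6 by 2.11 ± 0.12, H4C8 by 2.08 ± 0.08 and DOCK11 by 1.98 ± 0.11. The largest falls were those of PTGIS, at -1.94 ± 0.20, NRCAM at -1.74 ± 0.20, PRR9 at -1.65 ± 0.15, GZMA at -1.53 ± 0.12 and MUCL1 at -1.50 ± 0.22. The highest adjusted p among them was 0.00044.

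In A2780 the largest rises were all of histone genes. H2BC5 rose by 3.94 ± 0.07, from 8.44 to 12.38, H2AC6 by 3.73 ± 0.05, H3C6 by 3.63 ± 0.12, H2BC4 by 3.56 ± 0.14 and H2BC21 by 3.46 ± 0.12. The largest falls were those of CCNE2, at -2.86 ± 0.06, SPRY4 at -2.78 ± 0.10, from 10.24 to 7.46, MCM10 at -2.68 ± 0.06, SLCO4A1 at -2.55 ± 0.14 and SPRY4-IT1 at -2.51 ± 0.16. SPRY4-IT1 is a transcript that overlaps SPRY4, so both values are not independent. The highest adjusted p among them was 1.7e-08.

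The genes AURKA and AURKB code for targets of the compound. AURKB was lower in every line, with log2 changes of -0.48 ± 0.06 in MCF7, -0.31 ± 0.06 in MDA-MB-468, -1.26 ± 0.06 in HCT-116, -0.58 ± 0.06 in Colo205 and -1.69 ± 0.06 in A2780, each past the threshold. AURKA changed by -0.13 ± 0.05 in MCF7 (adjusted p 0.1, not past the threshold except with trend and robust settings), rose by 0.24 ± 0.05 in MDA-MB-468 and changed by -0.93 ± 0.05 in HCT-116, -0.34 ± 0.05 in Colo205 and -1.07 ± 0.05 in A2780. PLK1 rose by 0.34 ± 0.10 and CCNB1 by 0.29 ± 0.06 in MDA-MB-468. In MDA-MB-468 the call of PLK1 is lost without any of the 4 arrays, with changes of 0.27 without CTRL replicate 1, 0.40 without CTRL replicate 2, 0.39 without TRT replicate 1 and 0.29 without TRT replicate 2. The call of AURKA in that line is lost without CTRL replicate 1 (0.22) or TRT replicate 2 (0.21), that of CCNB1 without CTRL replicate 1 (0.21) and that of AURKB without CTRL replicate 2 or TRT replicate 2 (-0.26 each), and the other probe set of CCNB1 changed by 0.00 there. With the mean of probe sets the calls of AURKA (0.23), AURKB (-0.24) and CCNB1 (0.14) in that line are lost, and without a filter that of PLK1 (0.34). With the probe set of AURKA that is not marked as shared, whose mean level of 4.81 is near background, the calls of AURKA are lost in MDA-MB-468 (0.27), HCT-116 (-0.65), Colo205 (-0.25) and on average (-0.21). In HCT-116, Colo205 and A2780 both were lower, PLK1 at -0.80, -0.38 and -1.20 and CCNB1 at -0.66, -0.35 and -1.03. In MCF7, neither PLK1 (0.07, adjusted p 0.68) nor CCNB1 (-0.09, adjusted p 0.3) passed the threshold. CDKN1A rose in every line, by 0.65 ± 0.07 in MCF7, 1.01 ± 0.07 in MDA-MB-468, 1.47 ± 0.07 in HCT-116, 0.28 ± 0.07 in Colo205 and 2.11 ± 0.07 in A2780. In Colo205 its call is lost without CTRL replicate 1 (0.21) or TRT replicate 2 (0.25), and that of PLK1 without CTRL replicate 1 (-0.36) or TRT replicate 1 (-0.33). MDM2 rose by 0.70 ± 0.09 in MCF7, 1.84 ± 0.09 in HCT-116 and 1.18 ± 0.09 in A2780. In MDA-MB-468 (0.18, adjusted p 0.21) and in Colo205 (-0.23, adjusted p 0.075) MDM2 did not pass the threshold. In Colo205 it was called lower with trend and robust settings (-0.23) and without TRT replicate 2 of the line (-0.36).

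**Figure D2:**
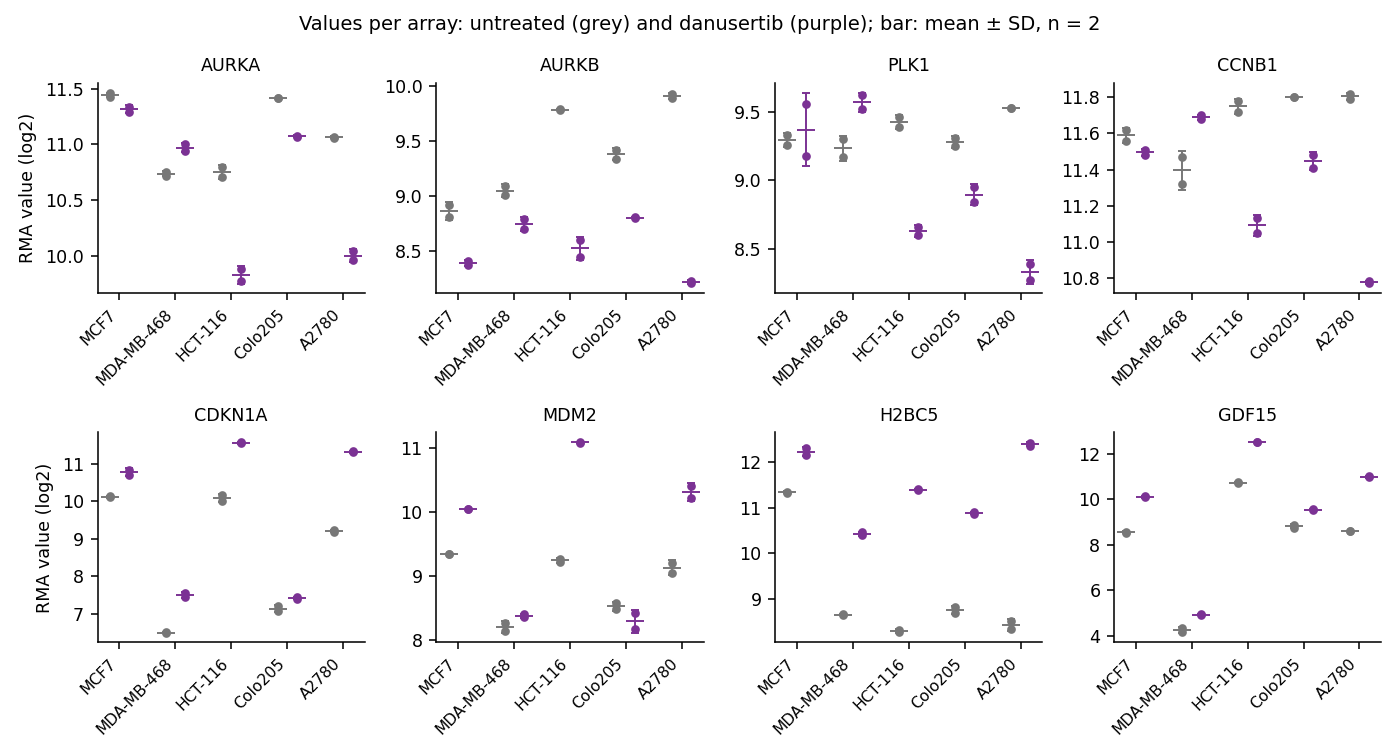
RMA values on the log2 scale (vertical axes, which do not start at 0) of 8 genes on each array, by cell line (horizontal axes), untreated in grey and danusertib-treated in purple, with mean and SD of n = 2. AURKB is lower and CDKN1A higher in treated cultures of every line, while MDM2 is higher by 1.84 in HCT-116 and is not higher in Colo205.

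The next question is which changes the lines share on average. Over the 5 lines, 6992 genes changed on average, with 3484 higher and 3508 lower (3627 and 3416 after renewed quantile normalisation, 3413 and 3561 after centring arrays on their medians), and 21 rose and 15 fell by at least 2-fold. With lines instead of arrays as replicates, limma called 0 genes, so the average describes these 5 lines. Each line was compared with its own untreated cultures, while all lines share an estimate of the spread. The number of genes higher in all 5 lines was 101, against 0.2 for independent calls, and the number lower in all 5 lines was 167, against 0.4. The sign of the change was the same in all 5 lines for 2981 genes, or 20.4%, against 6.25% by chance. Significant changes in opposite directions in different lines were seen for 1327 genes. Across genes, which are not independent replicates, log2 changes of pairs of lines correlated between 0.16, for MDA-MB-468 and A2780, and 0.54, for HCT-116 and A2780.

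Among genes with the same sign in all 5 lines, histone genes led the average rises, with H2BC5 at 2.36 ± 0.03, H3C6 at 2.25 ± 0.05, H2AC6 at 2.17 ± 0.02, H2BC21 at 1.83 ± 0.05, H4C8 at 1.54 ± 0.04, H2BC12L at 1.53 ± 0.03, H2BC9 at 1.5 ± 0.04, H2BC6 at 1.46 ± 0.03 and H1-2 at 1.45 ± 0.04. Histone genes resemble each other, and several of these probe sets are marked as shared, so the paralog behind a value is uncertain. GDF15 rose by 1.43 ± 0.03 on average. The largest average falls among such genes were those of MCM10, at -1.29 ± 0.03, CDC45 at -1.18 ± 0.02, HELLS at -1.18 ± 0.04, ZNF367 at -1.16 ± 0.03, RRM2 at -1.13 ± 0.02, EXO1 at -1.10 ± 0.02, UHRF1 at -1.07 ± 0.03, E2F8 at -1.03 ± 0.03, TCF19 at -1.03 ± 0.04 and POLE2 at -1.03 ± 0.02. All 20 genes named here moved the same way in all 5 lines, and their highest adjusted p was 4.5e-10. Among the other genes looked at in every comparison, the average changes were -0.45 ± 0.02 for AURKA, -0.86 ± 0.03 for AURKB, -0.39 ± 0.04 for PLK1, -0.37 ± 0.03 for CCNB1, 1.10 ± 0.03 for CDKN1A and 0.73 ± 0.04 for MDM2. Past the threshold, AURKA, CCNB1 and PLK1 were higher in 1 line, MDA-MB-468, and MDM2 in 3.

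Among the lists, G1/S and replication genes were lower in every line. The median log2 change of its 39 genes was -0.60 in MCF7, -0.32 in MDA-MB-468, -1.22 in HCT-116, -0.22 in Colo205 and -1.55 in A2780. Past the threshold were 39, 27, 39, 23 and 38 lower genes in these lines and 0 higher ones in any line. Adjusted over the list alone, 39, 30, 39, 26 and 39 were lower. Camera called the list in every line, and each call holds with an estimated correlation, the highest adjusted p being 0.00056. On average all 39 genes were lower, with a median of -0.79.

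Mitotic genes, 46 in number, went different ways in different lines. Their median was -0.83 in HCT-116, with 46 genes lower, -0.33 in Colo205, with 36 lower and 0 higher, and -1.04 in A2780, with 45 lower and 0 higher. These 3 calls hold with an estimated correlation, at adjusted p of at most 0.0018. In MCF7 the median was -0.09, with 13 genes lower and 4 higher (camera adjusted p 0.01, and 0.28 with an estimated correlation), and this call is also lost with the stricter filter and without CTRL replicate 2 or TRT replicate 2 of the line (-0.09 each). In MDA-MB-468 the median was 0.11, with 16 genes higher and 2 lower (8.5e-06, and 0.059 with an estimated correlation). Adjusted over the list alone, 18 were lower and 6 higher in MCF7, 19 higher and 2 lower in MDA-MB-468, 46 lower in HCT-116, 41 in Colo205 and 45 in A2780. The rises with the smallest adjusted p in MDA-MB-468 were those of DLGAP5 (0.44), BUB1 (0.44), PTTG1 (0.36) and NEK2 (0.53), and KIF14 and CDC25C (0.45 each), named after their values were seen, rose by more than the first 3 of these.

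The median change of 37 p53 targets was 0.35 in MCF7, 0.08 in MDA-MB-468, 0.83 in HCT-116, 0.07 in Colo205 and 1.23 in A2780. The numbers of these genes past the threshold were 22 higher and 1 lower in MCF7, 10 higher and 2 lower in MDA-MB-468, 33 higher and 0 lower in HCT-116, 9 higher and 5 lower in Colo205, and 35 higher and 1 lower in A2780. Adjusted over the list alone, 26, 11, 34, 9 and 35 were higher and 1, 3, 0, 6 and 1 lower. The calls by camera in MCF7, HCT-116 and A2780 hold with an estimated correlation, at adjusted p of at most 0.00021. In MDA-MB-468 the adjusted p was 0.039, and 0.16 with an estimated correlation. That call is also lost with the stricter filter (0.08), the mean of probe sets (0.03), the replicate block (0.08), only probe sets not marked as shared (0.05), and without CTRL replicate 1 or TRT replicate 1 of the line (0.09 each). In Colo205 it was 0.12, and the list came past the threshold without CTRL replicate 2 of the line (0.11). The median in Colo205 was 0.02 without TRT replicate 1 and 0.12 without TRT replicate 2. Fry, which does not compare the list with other genes, gave p-values for a shift in 1 direction of 0.00053 in MDA-MB-468 and 0.00028 in Colo205. GDF15 rose in every line, by 0.67 in MDA-MB-468, 0.74 in Colo205, 1.79 in HCT-116 and 2.38 in A2780 besides MCF7. In MDA-MB-468, however, GDF15 lay between 4.16 and 4.94 on all 4 arrays, below the filter of 5.13 and near background, and its other probe sets changed by 0.09 and -0.36 there. TP53I3 rose by 0.96 in Colo205 and 2.46 in A2780.

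Histone genes rose in every line. The median of 14 genes was 0.72 in MCF7, 1.17 in MDA-MB-468, 0.94 in HCT-116, 1.30 in Colo205, 2.67 in A2780 and 1.43 on average. In HCT-116 the median was 0.16 with only probe sets not marked as shared, where 3 of 7 genes were higher. It ranged from 0.16 to 1.49 over all alternatives run for lists. Of the 14 genes, 11, 12, 9, 12 and 13 were higher past the threshold in the 5 lines in that order, while 1 was lower in MCF7 and 1 in HCT-116. Adjusted over the list alone, 12, 12, 9, 13 and 13 were higher. Each call holds with an estimated correlation, at adjusted p of at most 0.00054.

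**Figure D3:**
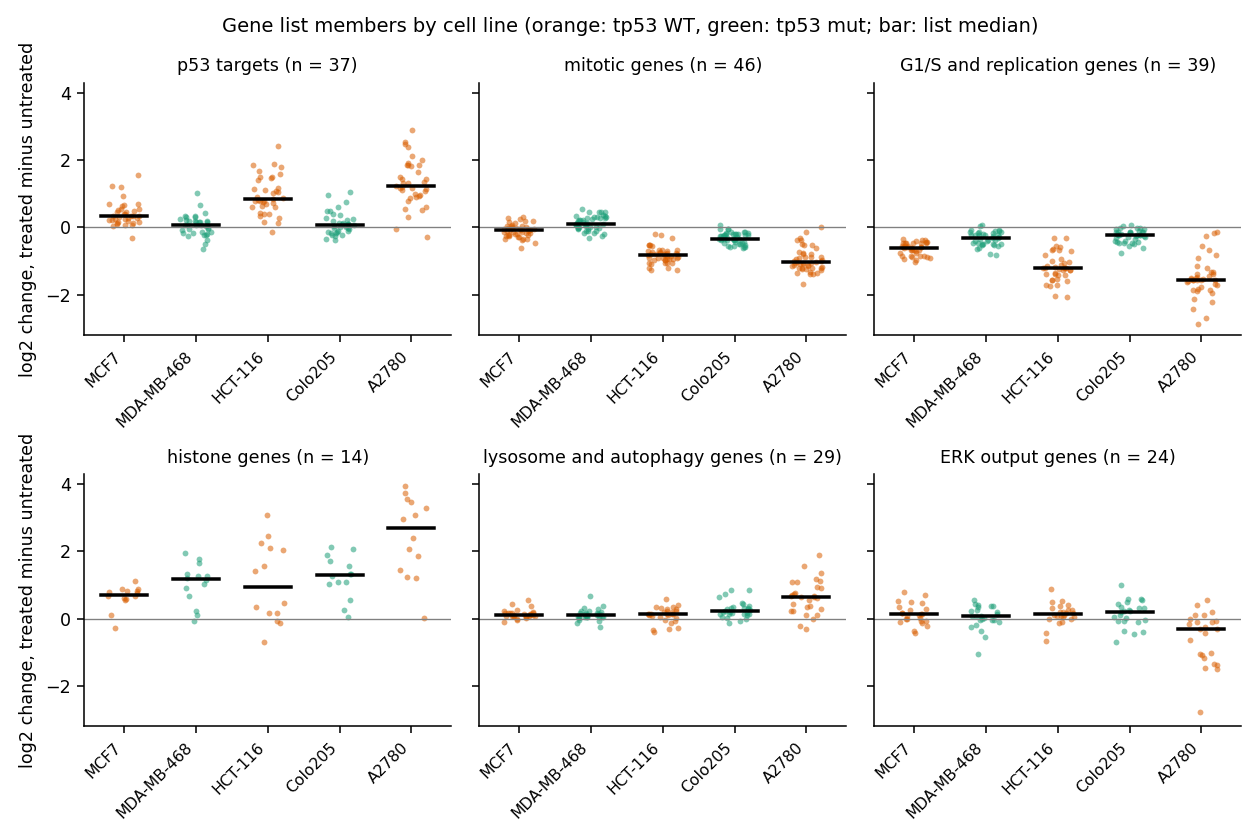
Log2 change, treated minus untreated (vertical axes), of each gene (dots) in 6 lists by cell line (horizontal axes), with the list median as a bar, tp53 WT lines in orange and tp53 mut lines in green. The median of G1/S and replication genes lies between -1.55 and -0.22 and that of histone genes between 0.72 and 2.67, while that of p53 targets is 0.35 to 1.23 in tp53 WT lines and 0.07 to 0.08 in tp53 mut lines.

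Lysosome and autophagy genes, 29 in number, had medians of 0.12 in MCF7, 0.12 in MDA-MB-468, 0.14 in HCT-116, 0.24 in Colo205 and 0.65 in A2780. Camera called all 5 at the preset correlation. With an estimated correlation the calls hold in Colo205 (0.036), A2780 (0.033) and on average (median 0.22, adjusted p 0.031), and they are lost in MCF7 (0.12), MDA-MB-468 (0.14) and HCT-116 (0.35). The call in HCT-116 is also lost without CTRL replicate 2 (0.10) or TRT replicate 1 (0.14) of the line and with only probe sets not marked as shared (0.13). LAMP2 led them in A2780, with a rise of 1.89. Cholesterol synthesis genes, 19 in number, had medians of 0.17 in MDA-MB-468, where 7 were higher and 0 lower, and -0.44 in HCT-116, where 14 were lower and 1 higher. Both calls hold with an estimated correlation (0.01 and 0.005), as does that in Colo205, with a median of -0.13 (0.048). The calls in A2780 (median -0.30) and on average (-0.15) are lost with it (0.08 and 0.099), that on average also without line HCT-116 (-0.08), and the list was not called in MCF7. INSIG1 led the falls, at -1.81 in HCT-116, -1.20 in Colo205 and -1.09 in A2780.

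ERK output genes, transcripts that follow the activity of the kinase ERK, had a median of -0.30 in A2780, with 12 of 24 lower and 2 higher (camera adjusted p 0.0015, and 0.027 with an estimated correlation). Over all alternatives run for lists this median ranged from -0.46 to -0.28. In no other line was the list called in the reported analysis. Under some alternatives it was called higher, in HCT-116 with the mean of probe sets (0.14), the replicate block (0.14) and only probe sets not marked as shared (0.17), in Colo205 with the mean of probe sets (0.17) and only probe sets not marked as shared (0.28), and in MCF7 without CTRL replicate 2 (0.10) or TRT replicate 1 (0.20) of the line. The falls in A2780 with the smallest adjusted p were those of SPRY4 (-2.78), EGR1 (-1.39), SPRED2 (-1.17) and MYC (-1.03). By size, ETV4 (-1.51) and DUSP5 (-1.48), named after their values were seen, followed SPRY4. Integrated stress and ER stress genes had a median of -0.16 in MDA-MB-468, with 10 of 27 lower and 1 higher (1.5e-05, and 0.01 with an estimated correlation), and of -0.12 on average (0.04, and 0.13 with an estimated correlation). The call on average is also lost without line MDA-MB-468 (-0.06), MCF7 (-0.10) or Colo205 (-0.11), with the stricter filter, the replicate block or only probe sets not marked as shared (-0.12 each), and without MCF7 TRT replicate 2, MDA-MB-468 TRT replicate 2 or Colo205 CTRL replicate 2 (-0.11 each). In Colo205 the list was called only under no filter (-0.08), the mean of probe sets (-0.08) and without CTRL replicate 1 of the line (-0.10). ASNS was lower by its average change of -0.59, PSAT1 by -0.50 and ATF4 by -0.31. YAP/TAZ target genes had medians of -0.19 in MCF7 (0.01, and 0.11 with an estimated correlation, and lost with the stricter filter too) and -0.15 in MDA-MB-468 (0.0033 and 0.046). Apoptosis regulators had medians of 0.08 in MDA-MB-468 (0.015 and 0.045), 0.13 in HCT-116 (0.014 and 0.03) and 0.09 on average (0.02 and 0.042). These 3 calls depend on the processing. That in MDA-MB-468 is lost with the stricter filter (0.10) and without TRT replicate 2 of the line (0.04), that in HCT-116 with only probe sets not marked as shared (0.16), and that on average with these probe sets (0.09) and without line MDA-MB-468 (0.10) or Colo205 (0.11). Epithelial genes were called on average and in no single line, with a median of 0.10 (0.05 after rounding, and 0.086 with an estimated correlation). This call rests on the choice of processing. It is lost with the stricter filter (0.09), the mean of probe sets (0.10), renewed quantile normalisation (0.10) and only probe sets not marked as shared (0.09), and without line MCF7 (0.09), MDA-MB-468 (0.12), HCT-116 (0.10) or Colo205 (0.09). It is also lost without any of 13 single arrays (0.09 to 0.11), namely CTRL replicates 1 and 2 and TRT replicate 2 of MCF7, CTRL replicate 2 and TRT replicates 1 and 2 of MDA-MB-468, each array of HCT-116, and CTRL replicate 1 and TRT replicates 1 and 2 of Colo205. In HCT-116 the list was called without a filter (0.15), under both scalings (0.16 and 0.13) and with the replicate block (0.15), and in Colo205 with the block (0.12) and only probe sets not marked as shared (0.19). NF-kB and secretory inflammation genes, interferon response genes, estrogen response genes, the marker lists and reference genes were called in no line and not on average in the reported analysis. Under some alternatives calls appeared for NF-kB (0.06 to 0.08), basal breast markers (-0.12) and leukocyte markers (-0.16) in MDA-MB-468, interferon response genes in HCT-116 (0.18 to 0.30) and Colo205 (0.13), colon markers in Colo205 (0.26), and estrogen response genes (-0.16 to -0.11) and reference genes (-0.24) in A2780. The median, the mean and the camera direction differed in sign only for lists that were not called, such as estrogen response genes in HCT-116, with a mean of -0.10 and a median of 0.04.

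The comparison of 3 tp53 WT with 2 tp53 mut lines asks whether the response depends on tp53 status. With lines as replicates, limma called 0 genes, and 828 genes had an unadjusted p under 0.05. The smallest adjusted p was 0.8. The genes with the smallest p and a higher change in tp53 WT lines were FAS (difference 1.57 ± 0.22), ABCA1 (1.36 ± 0.21), BLNK (0.82 ± 0.13), PTGIS (1.44 ± 0.26) and KITLG (0.83 ± 0.15). Those with a lower change were KISS1R (-1.43 ± 0.20), BRCA1 (-1.06 ± 0.19), TYRO3 (-0.87 ± 0.16), CDCA7 (-0.95 ± 0.19) and MNS1 (-0.87 ± 0.18). None of these passed the threshold. The difference of PTGIS comes from falls in MDA-MB-468 (-1.12) and Colo205 (-1.94) on a probe set of mean level 5.44, near the filter. In MCF7, HCT-116 and A2780 it changed by -0.18, 0.10 and -0.19. Its other probe sets, at mean levels of 3.79 and 4.13, changed by -0.22 and 0.12 in MDA-MB-468 and by -0.95 and -1.04 in Colo205. The differences by tp53 status were 0.77 ± 0.44 for CDKN1A, 1.27 ± 0.34 for MDM2, -0.66 ± 0.32 for AURKA, -0.70 ± 0.35 for AURKB, -0.62 ± 0.40 for PLK1 and -0.56 ± 0.32 for CCNB1. These did not pass either. With arrays instead of lines as replicates, which leaves out the spread between lines, each gene named in this paragraph passes.

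Of the lists, camera at the preset correlation called p53 targets higher (median difference 0.71) and mitotic genes (-0.57), G1/S and replication genes (-0.84) and cholesterol synthesis genes (-0.28) lower in tp53 WT lines, and none of these 4 calls holds with an estimated correlation (adjusted p 0.83 to 0.84). The p-values by fry were 0.091 for p53 targets, 0.26 for mitotic genes, 0.068 for G1/S and replication genes and 0.4 for cholesterol synthesis genes. Counts adjusted over the list alone were 2 p53 targets higher and 16 G1/S and replication genes lower. With the list median of each line as its value, the mean for p53 targets was 0.80 in tp53 WT and 0.08 in tp53 mut lines (exact permutation test over 10 splits, two-sided p 0.2). The smallest p this design allows is 0.1. Every tp53 WT line was above both tp53 mut lines, the lowest tp53 WT line being at 0.35 and the highest tp53 mut line at 0.08.

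Within breast, MCF7 (tp53 WT) and MDA-MB-468 (tp53 mut) were compared directly, as a comparison of 2 lines that also differ in much else. The response differed for 996 genes, of which 406 had a higher and 590 a lower change in MCF7. This surplus of lower changes depends on the scaling, with 481 higher and 475 lower after renewed quantile normalisation and 318 and 859 after centring arrays on their medians. The largest positive differences were those of OLR1 (2.11 ± 0.19), CRISP3 (1.89 ± 0.24), GABRP (1.72 ± 0.16), EGR1 (1.54 ± 0.09) and TMEM52B (1.5 ± 0.10). The largest negative ones were those of HMCN1 (-1.50 ± 0.28), SGK1 (-1.44 ± 0.24), DLX2 (-1.44 ± 0.19), GJA1 (-1.39 ± 0.15) and RNF217 (-1.28 ± 0.27). The difference was 0.52 ± 0.12 for MDM2, -0.36 ± 0.09 for CDKN1A, -0.37 ± 0.07 for AURKA and -0.38 ± 0.08 for CCNB1, each past the threshold. It was -0.17 ± 0.09 for AURKB and -0.26 ± 0.14 for PLK1, which did not pass, except PLK1 without TRT replicate 1 of MCF7 (-0.45). The 4 calls depend on the processing. With replicate numbers as a block those of AURKA (-0.37), CDKN1A (-0.36) and MDM2 (0.52) are lost, without a filter that of CDKN1A (-0.36), and with the mean of probe sets those of AURKA (-0.17) and RNF217 (-0.50). With only probe sets not marked as shared CCNB1 loses its call (-0.23), and AURKA shows no negative difference on such a probe set, whose mean level of 4.81 is near background. The call of CDKN1A is lost without CTRL replicate 1 (-0.37), CTRL replicate 2 (-0.34) or TRT replicate 1 (-0.29) of MCF7, CTRL replicate 1 (-0.35), CTRL replicate 2 (-0.37) or TRT replicate 1 (-0.30) of MDA-MB-468, either treated array of HCT-116 or any array of A2780 (-0.36 each). That of MDM2 is lost without CTRL replicate 1, CTRL replicate 2 or TRT replicate 1 of MCF7 (0.52 each) or CTRL replicate 2 (0.46) or TRT replicate 1 (0.50) of MDA-MB-468. CCNB1 loses its call without CTRL replicate 2 (-0.35) or TRT replicate 1 (-0.36) of MCF7 or CTRL replicate 1 of MDA-MB-468 (-0.31), and RNF217 without TRT replicate 1 of MCF7 (-1.26) or CTRL replicate 2 (-1.01) or TRT replicate 1 (-1.17) of MDA-MB-468.

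Among the lists, p53 targets had a median difference of 0.34 between the breast lines, with 14 genes higher and 2 lower in MCF7. Mitotic genes had -0.23, with 12 lower, G1/S and replication genes -0.33, with 19 lower, and histone genes -0.44, with 8 lower, and no gene of these 3 lists was higher past the threshold over all genes. Adjusted over the list alone, 22 p53 targets were higher and 2 lower, 22 mitotic genes and 8 histone genes were lower and 0 higher, and 23 G1/S genes were lower and 1 higher. These 4 calls hold with an estimated correlation, at adjusted p of at most 0.011. With only probe sets not marked as shared, however, the difference in histone genes was -0.24 and its call is lost. The calls for cholesterol synthesis genes (-0.24) and for integrated stress and ER stress genes (0.09) are lost with an estimated correlation (0.07 and 0.15). That for integrated stress and ER stress genes is also lost with no filter (0.09), the mean of probe sets (0.09), centring of arrays (0.05) and only probe sets not marked as shared (0.08), and without CTRL replicate 2 (0.07) or TRT replicate 1 (0.09) of MCF7 or TRT replicate 2 of MDA-MB-468 (0.10).

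Within colon, HCT-116 (tp53 WT) and Colo205 (tp53 mut) differed in the response of 2382 genes, of which 1081 had a higher and 1301 a lower change in HCT-116. They were 1150 and 1300 after renewed quantile normalisation and 870 and 1456 after centring arrays on their medians. The largest positive differences were those of MDM2 (2.07 ± 0.12), PTGIS (2.05 ± 0.29), MUCL1 (2.01 ± 0.31), DNAI3 (1.98 ± 0.29) and NRCAM (1.89 ± 0.28). The largest negative ones were those of RNA45SN5 (-2.33 ± 0.21), DTL (-2.10 ± 0.07), MYB (-1.97 ± 0.10), CCNE2 (-1.94 ± 0.08) and H4C8 (-1.92 ± 0.11). The difference was 1.19 ± 0.09 for CDKN1A, -0.59 ± 0.07 for AURKA, -0.68 ± 0.09 for AURKB and -0.31 ± 0.08 for CCNB1, each past the threshold, and -0.41 ± 0.14 for PLK1 (adjusted p 0.059), which did not pass. PLK1 passes with the stricter filter (-0.41), centring of arrays (-0.44), trend and robust settings (-0.41) and without TRT replicate 1 or 2 of MCF7 (-0.41 each). The call of CCNB1 is lost without CTRL replicate 2 (-0.28) or TRT replicate 2 (-0.26) of HCT-116, without CTRL replicate 1 (-0.30) or TRT replicate 2 (-0.27) of Colo205 and with only probe sets not marked as shared (-0.22). With the mean of probe sets the calls of AURKA (-0.46) and AURKB (-0.28) are lost, and with only probe sets not marked as shared that of AURKA (-0.40).

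The colon lines differed in p53 targets by a median of 0.80, with 30 genes higher and 0 lower in HCT-116, in mitotic genes by -0.52, with 39 lower, and in G1/S and replication genes by -0.96, with 36 lower and 0 higher. Adjusted over the list alone, 31 p53 targets were higher and 0 lower, 42 mitotic genes were lower and 0 higher, and 37 G1/S genes were lower and 1 higher. These 3 calls hold with an estimated correlation, at adjusted p of at most 0.00056. The calls for lysosome and autophagy genes (-0.13) and cholesterol synthesis genes (-0.23) are lost with an estimated correlation (0.57 and 0.1), the former also with only probe sets not marked as shared (-0.10). Histone genes were not called, with 5 higher and 5 lower.

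The last comparison asks for any difference in response among the 5 lines. The moderated F test called 7537 genes, or 51.6% of those tested.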

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

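The gene and list results in the next 2 paragraphs are differences between lines in the response to danusertib, each tested directly as a difference of effects. The tests of explanations for the 3 patterns below, p53 targets, histone genes and ERK output genes, were chosen after the results were seen. The counts for other splits of the samples, and the comparisons of the breast and of the colon lines, were planned before the data were examined.

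The response of 996 genes differed between MCF7 and MDA-MB-468, that of 2382 genes between HCT-116 and Colo205, and that of 7537 genes varied among the 5 lines. In the breast lines the largest differences, MCF7 minus MDA-MB-468 on the log2 scale, were 2.11 for OLR1, 1.89 for CRISP3, 1.72 for GABRP, 1.54 for EGR1, 1.5 for TMEM52B, -1.50 for HMCN1, -1.44 for SGK1, -1.44 for DLX2, -1.39 for GJA1 and -1.28 for RNF217. Of the genes looked at in every comparison, AURKA (-0.37), CCNB1 (-0.38), CDKN1A (-0.36) and MDM2 (0.52) differed between the breast lines, calls that several alternatives given in the report end. In the colon lines the differences, HCT-116 minus Colo205, were 2.07 for MDM2, 2.05 for PTGIS, 2.01 for MUCL1, 1.98 for DNAI3, 1.89 for NRCAM, -2.33 for RNA45SN5, -2.10 for DTL, -1.97 for MYB, -1.94 for CCNE2 and -1.92 for H4C8, and AURKA (-0.59), AURKB (-0.68), CCNB1 (-0.31) and CDKN1A (1.19) differed too, of which the calls of AURKA, AURKB and CCNB1 are ended by alternatives given in the report.

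Among the lists, the median difference between the breast lines was 0.34 for p53 targets, -0.23 for mitotic genes, -0.33 for G1/S and replication genes, -0.44 for histone genes (-0.24 and not called with only probe sets not marked as shared), -0.24 for cholesterol synthesis genes and 0.09 for integrated stress and ER stress genes. With an estimated correlation the last 2 are not called (adjusted p 0.07 and 0.15), and the last is also lost under other alternatives given in the report. Between the colon lines it was 0.80 for p53 targets, -0.52 for mitotic genes, -0.96 for G1/S and replication genes, -0.13 for lysosome and autophagy genes and -0.23 for cholesterol synthesis genes, and the last 2 are not called with an estimated correlation (0.57 and 0.1). ERK output genes had a median of -0.48 in A2780 minus the mean of the other 4 lines (camera p 0.001 with an estimated correlation). This contrast was formed after the fall in A2780 was seen, and its p is not adjusted over the lists.

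The first pattern is that p53 targets rose more in the tp53 WT lines. For MCF7 a wider response in general does not account for it, since its log2 changes spread no more than those of Colo205 (SD 0.22 and 0.25). MCF7 still exceeded Colo205 by a median of 0.33 over the list (camera p 0.00053 with an estimated correlation). HCT-116 and A2780 had wider responses (SD 0.31 and 0.53) and the highest medians of the list (0.83 and 1.23). For these lines a wider response was not tested as an explanation. Tissue does not account for the pattern, because the difference was at least 0.34 within both tissues (camera adjusted p of at most 0.0015 with an estimated correlation). The pattern does not rest on A2780 alone. By the same list medians that show it, the mean of the other WT lines lay 0.51 above the higher mut line. Whether tp53 status itself is the cause cannot be told apart from other properties that divide these 5 lines the same way. The pattern itself is also uncertain, as the 10 splits allow no p under 0.1 and the exact permutation test gave 0.20. The difference of 0.72 was the highest in its direction. The largest of the other splits reached 0.86 in the opposite direction. It sets HCT-116 and A2780, the lines with the widest responses, above MCF7, MDA-MB-468 and Colo205. The list medians thus part the lines by width of response more than by tp53 status. CDKN1A, a p53 target, rose more in MDA-MB-468 than in MCF7 (-0.36, a call lost without 12 of the 20 arrays), so the pattern does not show in every gene of the list.

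The second pattern is the rise of histone genes. On average it does not rest on probe sets marked as shared. The 7 genes with probe sets not marked as shared had a median average change of 1.31, with 6 of them higher (camera adjusted p 1.4e-07). In HCT-116, however, the median of these genes was 0.16, with 3 of 7 higher, against 0.94 for the 14 genes of the reported analysis. The latter set holds more genes, so the contrast does not isolate an effect of shared probe sets. The mark does not show whether the remaining probe sets also bind RNA of similar paralogs, so cross-hybridisation stays open. Poorer RNA or a shift towards 3' ends in treated arrays was expected to raise the difference between 3' and 5' probe sets of both ACTB and GAPDH by more than 0.1. That of ACTB was higher in treated arrays of every line, but by at most 0.07, and that of GAPDH moved by -0.03 to 0.01. The histone medians rose by 0.72 to 2.67. These values argue against such a shift as the source of the rise, as far as ACTB and GAPDH show RNA quality. Histone transcripts usually lack a poly(A) tail and labelling commonly starts from it, so more polyadenylated histone RNA may underlie the rise of 1.31 as well as more histone RNA, and these arrays hold no test of either.

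The third pattern is the fall of ERK output genes in A2780. It is not confined to SPRY4 and its overlapping transcript, as 11 of the other 23 genes were lower in treated A2780 past the threshold and 2 were higher. Of all 14603 genes tested, 3616 were lower and 3787 higher in A2780, so any list would hold some lower genes. The count without SPRY4 was not tested against that share. A larger response of A2780 in general stays open. If A2780 only enlarged what the other lines do, the list would fall in these too, and the median of their mean change was 0.15 instead, but its rise does not pass with an estimated correlation (camera adjusted p 0.041 at the preset correlation and 0.11 with the estimated one, in the model of all 20 arrays). In single lines the rise is called only under some alternatives, such as Colo205 with only probe sets not marked as shared (0.28). In A2780 minus the mean of the other lines, DUSP5 (-1.70), ETV4 (-1.58), MAFF (-1.44) and ETV5 (-1.43), named after their values were seen, followed SPRY4 (-2.94). DUSP4 and SPRY1 hardly changed in A2780 (-0.11 and -0.09), and their differences come mostly from rises in the other lines (0.36 and 0.38). No test of ERK activity was run, and tissue and genotype of the line stay untested.

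For the average over lines, 1 of 100 splits of the arrays within lines, the real one, called 6992 genes or more. The highest of the others called 5404. A share of 1 in 100 makes chance unlikely as the source of the count but does not exclude it. Among the other splits, the 27 that part treated from untreated arrays of A2780 called 153 to 5404 genes and the 72 that do not called 0 to 48. The count thus depends largely on how A2780 is parted, so these splits cannot show whether the lines share an effect. For tp53 status, 828 genes had an unadjusted p under 0.05 in the real split and 1854 in the highest of the others, with 2 of 10 splits reaching 828, and 10 splits are too few for a share under 0.05.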

How the results depend on the processing

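The alternative with only probe sets not marked as shared was chosen after the data were seen, and all others before. With every probe set as a feature, 33117 instead of 14603 features were tested and counts rose to 3786 in MCF7, 3674 in MDA-MB-468, 6664 in HCT-116, 5286 in Colo205, 14740 in A2780, 13912 on average, 3827 for the colon lines and 13940 for any difference among lines. A fold of at least 1.5 left 266 genes in MCF7, 228 in MDA-MB-468, 850 in HCT-116, 408 in Colo205, 2969 in A2780, 308 on average, 279 for the breast lines and 881 for the colon lines. The fit to only the 4 arrays of a line has fewer residual degrees of freedom and called 365 genes in MCF7, 220 in MDA-MB-468 and 1004 in Colo205, and 2935 in HCT-116 and 7189 in A2780, within 1.5 times of the reported counts. Without the shared probe sets, 11567 genes were tested and 1557 changed in MCF7, 2046 in Colo205 and 617 in the breast lines. The breast count was 649 without a filter, where 19775 genes were tested, and 580 with replicate numbers as a block (replicate block), which has fewer degrees of freedom. Counts for all other results under no filter, the stricter filter, the mean of probe sets, both scalings, trend and robust settings and the block stayed within 1.5 times.

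With lines as replicates, 0 genes changed on average instead of 6992, and with arrays as replicates 4539 genes, 2162 higher and 2377 lower, differed by tp53 status instead of 0, because the spread between lines is then left out. Without A2780, 0 genes differed by tp53 status and 5012 changed on average. Centring arrays on their medians lowered the share of higher genes in the breast comparison from 40.8% to 27.0%, renewed quantile normalisation raised it to 50.3%, and the medians of all genes shifted by at most 0.02 under either scaling.

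Without a single array, where the remaining array of its group is assumed to vary like the other groups, 1277 to 1915 genes changed in MCF7, 1079 to 1229 in MDA-MB-468, 1991 to 2222 in Colo205, and 506 to 968 differed between the breast lines. Counts lower than reported by more than 1.5 times came without MCF7 CTRL replicate 2 (1284 in MCF7 and 566 for the breast lines), MCF7 TRT replicate 1 (1277 and 506), MDA-MB-468 CTRL replicate 1 (1079 in MDA-MB-468 and 581), CTRL replicate 2 (1134 and 574), TRT replicate 1 (1079 and 512) and TRT replicate 2 (1229), and without Colo205 CTRL replicate 1 (1991). The average stayed between 6678 and 6837, the colon lines between 1707 and 2428 and any difference among lines between 6743 and 7564.

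The median of p53 targets was 0.32 to 0.63 on average, 0.29 to 0.39 between the breast lines and 0.69 to 0.87 between the colon lines, past the threshold under every alternative run. By tp53 status it was 0.50 to 0.75, and 0.71 with an adjusted p of 0.83 with an estimated correlation, against 8.7e-20 at the preset one, because the estimate takes account of how the genes vary together between lines. Of 58 list results past the threshold, 1105 of 1183 values under alternatives stayed past it and 78 did not, and 40 values came past it among the others. With an estimated correlation 19 calls were lost. G1/S and replication genes and histone genes kept their direction and call in every line and on average under every alternative run for lists. ERK output genes on average turned from -0.02 (adjusted p 0.71) to 0.15 (0.011) without line A2780, with adjusted p of 0.011 to 0.77 over all alternatives. Histone genes by tp53 status turned from 0.34 (0.57) to -0.22 (0.048) without A2780, with 0.048 to 0.84 over all alternatives. Both follow from leaving out the line, whose medians are -0.30 and 2.67.

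Of 129 named gene results past the threshold, 2428 of 2515 values under alternatives stayed past it. AURKA between the breast lines turned from -0.37 (adjusted p 0.011) to 0.12 (0.9) with its probe set not marked as shared, whose mean level is 4.81, and the adjusted p over 28 alternatives was 0.00062 to 0.9. With that rule CCNB1 in MDA-MB-468 changed by 0.00 (0.99). Calls of single genes that are lost without an array are given with their values in the report. The call of CDKN1A between the breast lines was lost without 12 of the 20 arrays (-0.37 to -0.29).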

Other observations

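In MDA-MB-468 the median of G1/S and replication genes was -0.32 and that of mitotic genes 0.11, while both medians were negative in the other 4 lines, at -0.60 and -0.09 in MCF7. The mitotic calls in both breast lines are lost with an estimated correlation (adjusted p 0.059 in MDA-MB-468 and 0.28 in MCF7), and the difference between the lists was not tested.

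The ribosomal RNA precursor RNA45SN5 rose by 2.71 and 2.11 in Colo205 on its 2 probe sets. In the other lines the probe set with the higher level changed by -0.20 in MCF7, 0.50 in MDA-MB-468, 0.37 in HCT-116 and 0.42 in A2780. The transcript has no long poly(A) tail, and no test of its cause was run.

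TTC14, which is in no list, rose in all 5 lines, by 0.94 in MCF7, 1.02 in MDA-MB-468, 0.88 in HCT-116, 1.30 in Colo205 and 1.58 in A2780. It was named after its values were seen.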
